A study of Mus musculus with 2 samples.

How the data were processed

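Total RNA from differentiating 3T3-L1 cells was measured on Affymetrix Mouse Genome 430 2.0 arrays, 1 array for cells given a control siRNA and 1 for cells given an siRNA against Phf21a. Cultures were kept in DMEM with 25 mM glucose and 10% FBS, and biotin-labelled cRNA was made from 1 ug of total RNA. The groups were taken from the sample descriptions. The labels name no further cultures, so each group has n = 1.

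The deposited values are signal intensity on a linear scale, made by the authors with MAS5 according to the submitters' processing notes; its version is not given in the sources used here. MAS5 combines the probes of a probe set after background correction and mismatch subtraction, which leaves low signals noisy. On both arrays the mean without the lowest and highest 2% of probe sets was 500 after rounding, the trimmed-mean scaling of MAS5. Such scaling makes the arrays equal in total and cannot show a change in the amount of messenger RNA per cell. Detection calls were not used here.

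Of 45101 probe sets 64 were controls, 34945 mapped to 1 gene, 932 to several and 9160 to none. Gene symbols came from the array's probe annotation, and 34741 of the 34945 were matched to a gene table by Entrez number, which changed 0 symbols. No genome coordinates were used here. A probe set was called detected when its higher signal reached the median of all signals pooled over both arrays (51.3). Signals were raised to a floor, the pooled 25th percentile (12.9), before log2 was taken. Where a signal lay under the floor, the signals are given without a fold. Signals between the floor and the detection limit were used as they were, so log2 ratios against them are uncertain. Each gene was represented by its brightest detected probe set, leaving out those ending in _x_at where another existed. Of 18193 genes with a probe set 11301 were detected. The pooled 75th percentile (461) marked brighter genes.

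With 1 array per group no test and no p-value was computed. Genes were counted by size, at least 2-fold. The local spread beside a log2 ratio is the distance between the 16th and 84th percentiles, divided by 2, of log2 ratios among the 1000 detected genes or probe sets nearest in mean signal. The difference between 2 probe sets of a gene, as an SD divided by the square root of 2, gave a measure of disagreement between probe sets.

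Before the data were examined, 29 gene lists with 738 entries were fixed. They cover BHC and CoREST partners, adipogenesis, lipid and energy metabolism, cell cycle, stress, inflammation and markers of other cell types. Of these entries 51 had no probe set of 1 gene, and 15 genes were in more than 1 list. A list is described by the median log2 ratio of its detected genes, by its count of genes at least 1.5-fold higher or lower, and by the percentile of its median among 10000 random lists of equal size matched on mean signal in 20 bins. Lists of under 5 detected genes have no percentile. A percentile describes these 2 arrays, since genes are not replicates.

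The genes named were set by a rule fixed before the data were examined. It takes Phf21a, all detected members of the BHC and CoREST list and of the energy expenditure list, and the 12 highest and 12 lowest among genes whose higher signal reached the 75th percentile and whose detected probe sets agree in sign. It adds the members with the largest absolute log2 ratio of each other list, up to 4 where the list's median lay under the 2.5th or over the 97.5th percentile and up to 2 elsewhere. Another 22 genes were chosen after their values were seen.

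The procedure was tested on simulated data of 11301 genes with noise like that of these arrays. Of genes with a true log2 ratio of 1.5 or -1.5, 88% and 84% passed 2-fold, and all with 2.5 or -2.5 did, but so did 8.09% of unchanged genes. The noise was drawn from the local spread, which includes any true changes, so the 8.09% is no rate of false calls. Of 100 unrelated lists 2% lay outside the central 95%, against 95% of 20 lists raised by 0.5. The simulated lists were random genes with independent noise, which does not cover lists of genes that vary together.

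Alternatives set before the data were examined were median centring, quantile normalization, loess, a higher floor, a pseudocount of 1 in place of the floor, the mean over probe sets, leaving out suffixed probe sets (those ending in _x_at, _s_at or _a_at), a stricter and no detection limit, cutoffs of 1.5-fold and 3-fold, agreement of all probe sets, unmatched random lists, and lists without shared genes. Scaling to the poly-A and to the hybridisation controls was added after the data were seen. Centring and control scaling move a list and its random lists nearly alike, so they are left out where alternatives are counted for a list's percentile, as are those that leave under 5 genes. The analysis used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.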

Results

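Gene expression was measured in 3T3-L1 cells, a mouse preadipocyte line that turns into fat cells when given insulin, dexamethasone and 3-isobutyl-1-methylxanthine. Preadipocytes received an siRNA against Phf21a or a control siRNA (siGL3, directed at luciferase), were induced 24 h later, and were harvested after a further 24 h, early in adipogenesis. Phf21a encodes BHC80, a histone-reading subunit of the BHC corepressor complex, in which the histone demethylase LSD1 (Kdm1a) works with CoREST and the histone deacetylases. The comparison asks how the early adipogenic transcriptome differs when Phf21a is reduced. Each group held 1 array, so no value has a replicate error and no test was run. Their number limits the precision: each log2 ratio (Phf21a siRNA over control siRNA) is given ± a local spread, the scatter among the 1000 genes nearest in signal. That spread describes 1 array set against 1 array, includes any true changes, and is not the spread between cultures. "Higher" and "lower" always refer to the Phf21a siRNA array relative to the control array. Of 45101 probe sets on the array, 23901 were detected, and these represented 11301 genes. Median signals were 52.98 on the control array and 49.51 on the Phf21a siRNA array, and the 75th percentiles were 462 and 460.

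Phf21a (Entrez gene 192285) was 2.51-fold lower in the Phf21a siRNA array, with a signal of 306 against 768 (log2 ratio -1.33 ± 0.51). The other detected probe sets of the gene were lower too, the brighter with signals of 592 and 233 (log2 ratio -1.35) and the dimmer with 111 and 67.0 (-0.73). A further probe set was under the detection limit on both arrays at 39.2 and 43.8.

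Partners of the protein differed in direction. Rcor1, which encodes the CoREST scaffold of the complex, was lower by a log2 ratio of -1.32 ± 0.52 (939 to 376), and its 3 probe sets ranged from -1.62 to -1.01. Hdac1, a catalytic deacetylase of the complex, was 1.87-fold lower on its only detected probe set (4439 to 2377, -0.90 ± 0.39). Kdm1a, the demethylase itself, differed by less than its local spread (2927 to 3628, 0.31 ± 0.39). Among the 12 detected members of the BHC and CoREST list, 1 was at least 1.5-fold higher and 3 were at least 1.5-fold lower. The list had a median log2 ratio of 0.02 and a mean of -0.14, so the sign depended on the summary. Its median stood at percentile 45.0 of matched random lists.

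The remaining members past 1.5-fold were Hmg20b (0.62 ± 0.53) and the dim Rcor2 (115 to 72.7, -0.66 ± 0.72), the latter within its spread. Log2 ratios were 0.40 for Gse1, -0.41 for Zmym2 and 0.40 for Kdm1b. Rest, which encodes the repressor that recruits this complex to neuronal genes, was at -0.04, although its 4 probe sets reached 0.63. Hdac2 was at -0.41 on its brightest probe set while another gave 0.42. Zmym3 was at 0.19 with probe sets from -0.66 to 0.22, and Rcor3 at 0.09 with probe sets up to 1.92.

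**Figure D1:**
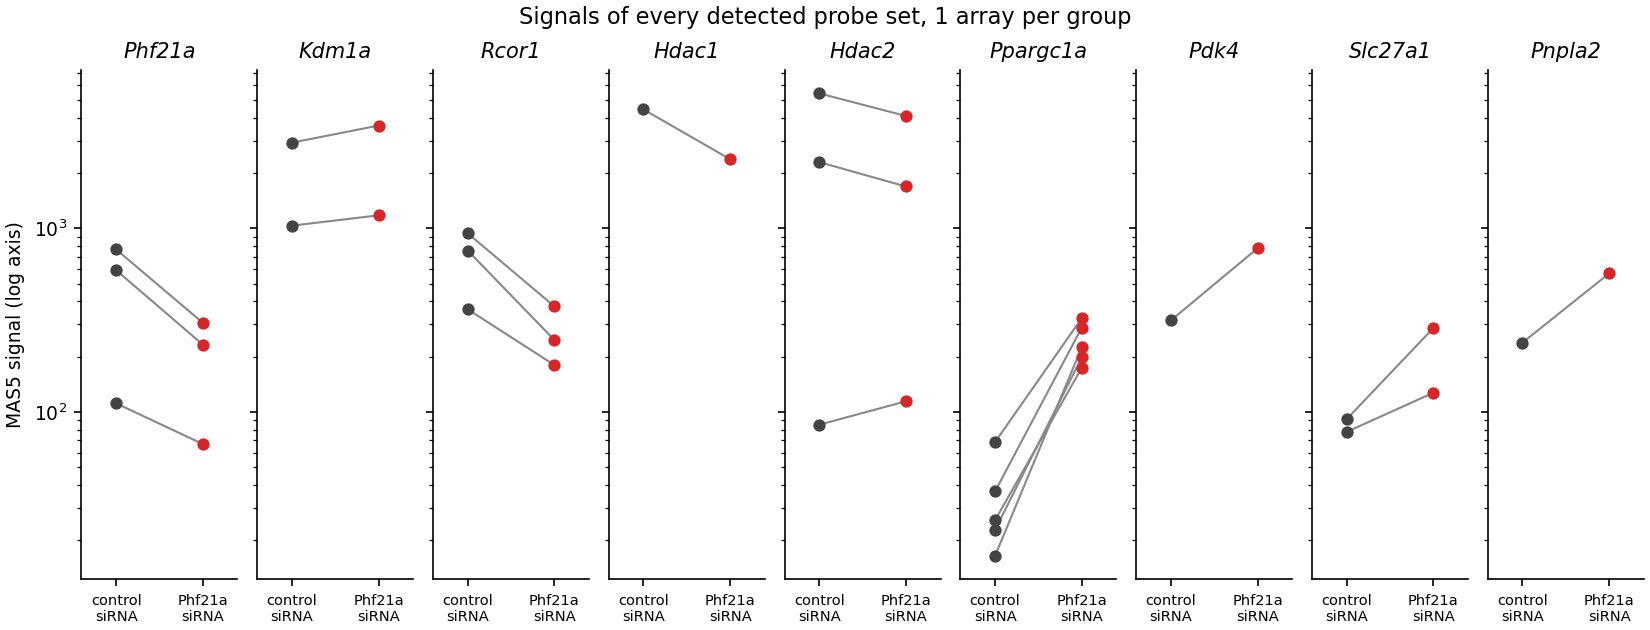
Signals of every detected probe set of 9 genes on a log axis, control siRNA on the left of each panel and Phf21a siRNA on the right, with a line joining the values of 1 probe set (1 array per group, no error bars). All detected probe sets of Phf21a and Rcor1 slope down and all 9 detected probe sets of Ppargc1a, Pdk4, Slc27a1 and Pnpla2 slope up, whereas those of Hdac2 go both ways.

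Genes of energy expenditure tied to LSD1 in fat cells were higher. Ppargc1a, the coactivator that drives mitochondrial and oxidative gene programmes, was 4.73-fold higher (Entrez gene 19017, 68.6 to 324, log2 ratio 2.24 ± 0.64). Slc27a1, a fatty acid transporter, was 3.13-fold higher (Entrez gene 26457, 91.4 to 286, 1.65 ± 0.63). Pdk4, the kinase that restrains pyruvate dehydrogenase, was 2.47-fold higher (Entrez gene 27273, 315 to 778, 1.30 ± 0.51). Pnpla2, which encodes adipose triglyceride lipase, was 2.38-fold higher (Entrez gene 66853, 238 to 568, 1.25 ± 0.52). Every log2 ratio exceeded its local spread, which covers only the central 68% of genes of like signal. All 9 detected probe sets of the 4 genes were at least 1.5-fold higher, against 14.2% of all detected probe sets. Of the 9, 5 belong to Ppargc1a, so they are not separate observations. The 5 probe sets of Ppargc1a lay between 2.24 and 3.77, with control signals of 4 of them under the detection limit of 51.3, and those of Slc27a1 between 0.71 and 1.65, while a second Pnpla2 probe set was undetected and went the other way (35.7 to 20.3). The median of the 4 genes was 1.48, and 0.75 when the arrays were scaled to the poly-A controls, which left 2 of the 4 at least 1.5-fold higher. They were picked from knowledge of related work on LSD1 in this cell line, which may have used these samples, so their direction is not independent evidence.

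Of the 16 thermogenic genes on the array 6 were detected, Ppargc1a among them. Of these 6, 3 were at least 1.5-fold higher and 0 lower, and the median of 0.52 stood at percentile 92.5. Besides Ppargc1a, those higher were Esrra, a nuclear receptor that Ppargc1a coactivates (497 to 804, 0.70 ± 0.53, picked after its value was seen), and the dim Cox7a1, a heart and brown fat cytochrome oxidase subunit. Cox7a1 had signals of 14.3 and 66.7, the former under the detection limit, and was at 0.38 with both raised to it, which left 2 of the 6 at least 1.5-fold higher.

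Genes of oxidative metabolism were higher by small amounts. The 22 detected genes of fatty acid oxidation had a median log2 ratio of 0.28 (percentile 97.8), with 19 above 0, 3 at least 1.5-fold higher and 1 lower. Acads (0.61 ± 0.46) and Acadl (0.59 ± 0.34), acyl-CoA dehydrogenases of mitochondrial beta-oxidation, were higher, and so was Acot2 (0.79 ± 0.58), whose second probe set gave -0.41. Acaa1a, a peroxisomal thiolase, was lower (-0.92 ± 0.59). Oxidative phosphorylation had a median of 0.15 over 72 genes (percentile 99.6), with 56 above 0, 3 at least 1.5-fold higher and 1 lower. Ndufs5 (0.71 ± 0.40) and Ndufs7 (0.59 ± 0.39) of complex I and Atp5e (0.59 ± 0.36) of the ATP synthase were higher, whereas Atp5g1 of the same synthase was lower (-0.84 ± 0.39). Mitochondrial biogenesis genes had a median of -0.03 over 20 genes (percentile 24.1), with 1 at least 1.5-fold higher and 1 lower. Tfb2m was at -0.74 ± 0.45 and Mterf4 at 0.64 ± 0.53. The fatty acid oxidation median lay inside the central 95% of random medians when probe sets were averaged, oxidative phosphorylation did when suffixed probe sets were left out, and both did against unmatched random lists.

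Lipid storage genes went both ways. Plin4, a lipid droplet coat protein, was 2.83-fold higher (470 to 1333, local spread 0.51), and Fabp4, the adipocyte fatty acid binding protein, was 1.67-fold higher (3502 to 5849, 0.74 ± 0.35). Plin2, another droplet coat protein, was 1.71-fold higher (0.77 ± 0.37). Dgat2, which makes triglyceride, was 3.39-fold lower (587 to 173, -1.76 ± 0.56) and Adipor2, an adiponectin receptor, 2.75-fold lower (1646 to 598, -1.46 ± 0.47, second probe set -0.70). Lpin1, a phosphatidate phosphatase, was at -1.11 ± 0.61 with a second probe set at -0.31, and Angptl4, an inhibitor of lipoprotein lipase, at -0.59 ± 0.52, while Gpat3, an earlier enzyme of that route, was 2.68-fold higher (127 to 340, 1.42 ± 0.60). Retn (9.82 to 70.9) and Slc2a4, the insulin-responsive glucose transporter (70.8 to 8.99), were each detected on 1 array and close to the limit there, with a local spread of 1.26. The lipid storage and secreted gene list had 4 of 18 genes at least 1.5-fold higher and 5 lower (median -0.19, percentile 7.34), Retn and Slc2a4 among them. With signals raised to the detection limit 3 were higher and 4 lower (percentile 4.17). Fatty acid and triglyceride synthesis had 2 of 19 higher and 4 lower (median -0.16, percentile 6.65).

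Regulators of adipogenesis were likewise mixed. Pparg, the master regulator of fat cell differentiation, was 1.59-fold higher (512 to 814, 0.67 ± 0.53), and Cebpb, an early inducer, was at -0.0033 ± 0.29 on its brightest probe set (7761 and 7743) and at -0.32 on the other. Dlk1, which keeps preadipocytes undifferentiated, was 2.07-fold lower (12290 to 5940, -1.05 ± 0.29, second probe set -1.78), and Klf2, a repressor of Pparg, was 2.56-fold higher (178 to 456, 1.35 ± 0.57). Among pro-adipogenic transcription factors 2 of 19 were at least 1.5-fold higher and 3 lower (median -0.17, percentile 8.28). Those higher were Pparg and Stat5b (0.66 ± 0.58, second probe set 0.06), and those lower were Ebf2 (-0.93 ± 0.72), Klf4 (-0.59 ± 0.51) and the dim Zfp423. Zfp423, like Ebf2 a mark of committed precursors, had signals of 63.7 and 36.1, the latter under the detection limit, and was at -0.31 with both raised to it. The preadipocyte and anti-adipogenic list had 1 of 17 genes higher and 4 lower (median 0.17, percentile 80.6). Plin4, Fabp4, Plin2, Adipor2, Lpin1, Angptl4, Pparg, Cebpb, Stat5b and Klf4 were picked after their values were seen.

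Across the transcriptome, 640 detected genes (5.66%) were at least 2-fold higher and 615 (5.44%) at least 2-fold lower, with 10046 in between. The median log2 ratio was 0.03 and signals correlated across genes at r = 0.95, where genes are not independent replicates. Scatter depended on signal. The local spread was 1.25 below a mean signal of 64, and there 18.5% of genes were 2-fold higher and 23.3% lower. It was 0.23 above 8192. Among the 7134 brighter genes 256 were higher and 237 lower. Probe sets of the same gene disagreed by 0.40 on the log2 scale over 5597 genes. They were read from the same 2 samples, so this does not cover the spread between cultures. Of 419 genes past 2-fold with a second detected probe set, 90.2% had that probe set in the same direction and 46.8% had it past 2-fold as well. All detected probe sets passed 2-fold in 71 genes that were higher and 79 that were lower.

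Among the 5469 brighter genes whose probe sets agreed in sign, the 12 highest were 4.22-fold to 10.1-fold higher. Fam107a, an actin-associated protein, was highest (107 to 1085, 3.34 ± 0.56). It was followed by Aldh1a1, a retinaldehyde dehydrogenase (75.3 to 625, 3.05 ± 0.59), Serpinb8, a protease inhibitor (107 to 863, 3.02 ± 0.57), and Havcr2, an immune checkpoint receptor (107 to 764, 2.83 ± 0.57). Megf10, an engulfment receptor, was at 2.48 and Hsd3b7, an enzyme of bile acid synthesis, at 2.39. The others, in falling order from 2.31 to 2.08, were Sgsm2, Fam102a, Enpp5, Gm20559, Uap1l1 and Dyrk3.

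The 12 lowest of the same genes were at least 4.28-fold lower. Inafm2 was 9.50-fold lower (793 to 83.5, -3.25 ± 0.58). Arhgap19 had signals of 483 and 47.1, the latter under the detection limit, and was at -3.24 with that signal raised to it, so the order of this pair is not known. Medag (1004 to 128, -2.98 ± 0.53) and Apmap (1463 to 201, -2.86 ± 0.53), both linked to adipocyte differentiation, came next. Gja1, a gap junction connexin, went from 5107 to 726 (-2.82 ± 0.46), with 6 probe sets from -4.25 to -0.91. E2f4, a cell cycle transcription factor, was at -2.74, the water channel Aqp1 at -2.65 and Ramp3, a receptor accessory protein, at -2.49. Rbmx, an RNA-binding protein, was at -2.41, the ubiquitin-conjugating enzyme Ube2n at -2.25, the phosphatase Ctdsp2 at -2.15 and the cytokine Il11 at -2.10. Of these 24 genes 12 had several probe sets, which all passed 2-fold in 9. Other probe sets came as close to 0 as -0.35 for Rbmx and -0.21 for Ctdsp2.

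**Figure D2:**
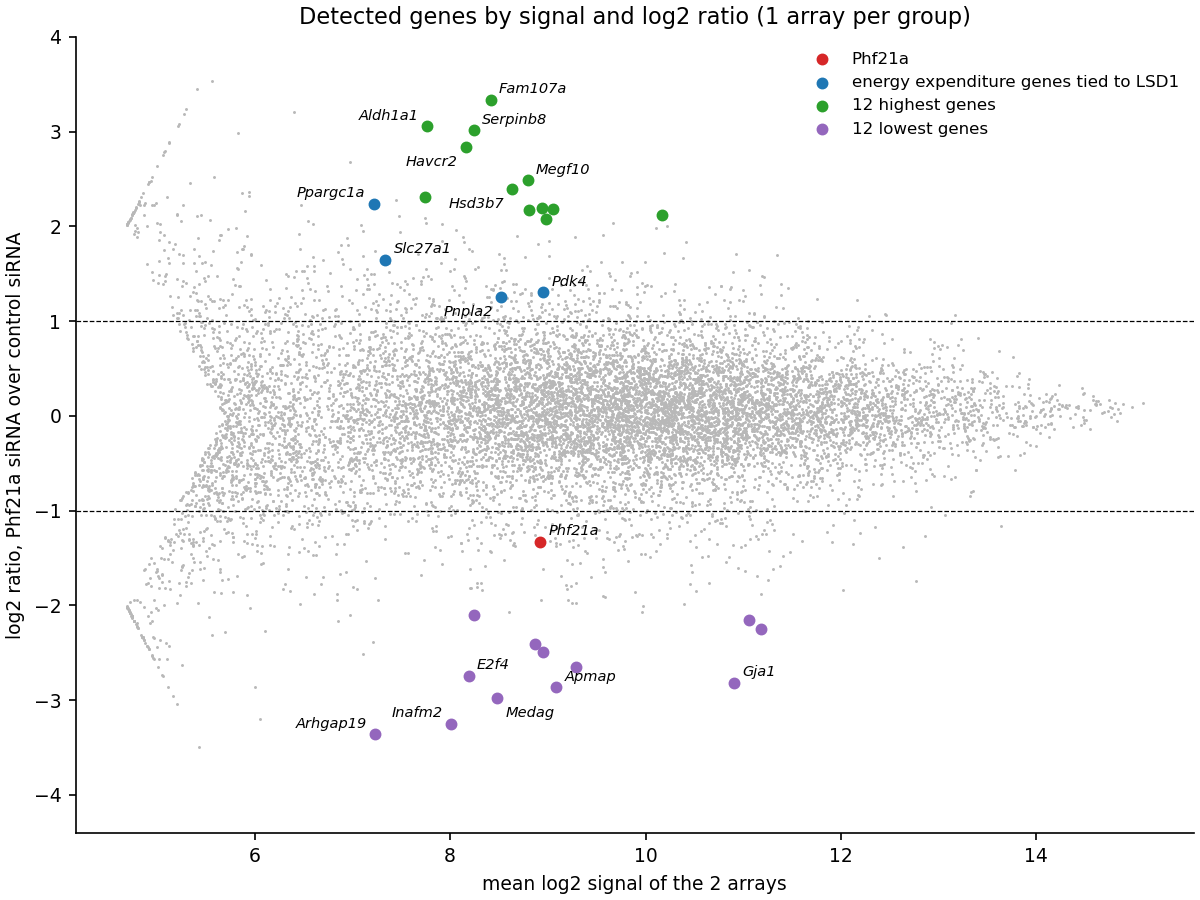
Log2 ratio of Phf21a siRNA over control siRNA against mean log2 signal for the 11301 detected genes, 1 point per gene and 1 array per group, with dashed lines at 2-fold. Phf21a lies at -1.33, the 4 energy expenditure genes between 1.25 and 2.24, the 12 highest and lowest are those of the brighter genes, and the scatter widens toward low signal; the slanted edges at the far left come from the floor put under low signals.

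DNA replication genes were lower by small amounts. Over 30 genes the median log2 ratio was -0.19 (percentile 0.22), with 7 above 0, 1 at least 1.5-fold higher and 4 lower. Rrm1 (5888 to 3208, -0.88 ± 0.37) and Rrm2 (-0.68 ± 0.33), the ribonucleotide reductase subunits, were lower, as were Mcm5 of the replicative helicase (-0.76 ± 0.38) and Ccne1, cyclin E1 (-0.65 ± 0.52). Mitosis genes had a median of -0.08 over 35 genes (percentile 5.75), with 0 higher and 3 lower. The lowest were Aurkb (873 to 415, -1.07 ± 0.52) and Cdc25c (-0.85 ± 0.56, second probe set -0.24).

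The p53 targets and CDK inhibitors had a median of 0.34 over 21 genes (percentile 99.3), with 4 at least 1.5-fold higher and 2 lower. Cdkn1a, which encodes the CDK inhibitor p21, was 1.76-fold higher (2420 to 4258, 0.82 ± 0.40). Btg2, an antiproliferative gene, was at 1.08 ± 0.52, but its second probe set gave -0.05. The members furthest from 0 were lower: Zmat3 (1154 to 339, -1.77 ± 0.52) and Ei24 (-1.13 ± 0.46), both p53-induced genes, went against the median of the list. The median stayed above the central 95% in 10 of 10 alternatives, and that of DNA replication stayed below it in 9 of 10, the exception being unmatched random lists at percentile 2.54.

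In the list of inflammatory cytokines and NF-kB targets 7 of 19 genes were at least 1.5-fold lower and 3 higher, with a median of -0.27 (percentile 1.34). The chemokine Ccl7 was 3.42-fold lower (2598 to 759, -1.78 ± 0.46), Cxcl5 2.69-fold lower (4044 to 1502, -1.43 ± 0.43) and Cx3cl1 4.31-fold lower (262 to 60.8, -2.11 ± 0.71). Cxcl1 (4920 to 1972, -1.32 ± 0.40) and Ccl2 (3880 to 1678, -1.21 ± 0.43), picked after their values were seen, were lower too. The dim Ccl5 had signals of 19.5 and 68.3, the former under the detection limit. The median of the list stayed below the central 95% in 9 of 10 alternatives, the exception being no filter on low signals.

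Interferon response genes were higher in number, with 11 of 24 at least 1.5-fold higher and 3 lower (median 0.51, percentile 99.8). Most were dim. Ifi35 was bright and 2.75-fold higher (1433 to 3946, 1.46 ± 0.42), whereas Psmb8, an immunoproteasome subunit (14.9 to 59.7), Irf7 (19.3 to 54.2) and Oasl1 (66.4 to 22.1) each had 1 signal under the detection limit and the other close to it. The median lay inside the central 95% in 4 of 10 alternatives, among them the stricter detection limit, where it was 0.21, and under both scalings to control RNAs.

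Leukocyte markers, which bear on both of these immune lists, were detected in 7 of 15 cases. Of these 4 were at least 1.5-fold higher and 1 lower, with a median of 0.75 (percentile 98.4). Csf1r was at 1.18 ± 0.57 on its brightest probe set (200 to 452), and its 3 probe sets ranged from 0.18 to 1.18. Cd68 (64.0 to 119, 0.89 ± 0.70) and Cd14 (479 to 804, 0.75 ± 0.51, picked after its value was seen) were higher too. The dim Fcer1g (25.7 to 54.4) and Laptm5 (66.4 to 22.3) each had 1 signal under the detection limit. The pan-leukocyte gene Ptprc was undetected at 3.07 and 0.486, as were Tyrobp (4.66 and 6.32) and Cd52 (1.61 and 3.87), and the macrophage lysozyme Lyz2 was at 53.6 and 71.9. The median lay inside the central 95% in 4 of 9 alternatives and under hybridisation scaling. With averaged probe sets it was 0.53 (percentile 94.7), with 3 of 7 higher.

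Extracellular matrix genes included several of the bright genes with low ratios. Nid1, a basement membrane linker, was 3.35-fold lower (12783 to 3820, -1.74 ± 0.29) and its 3 probe sets ranged from -2.46 to -0.93. Dcn, the proteoglycan decorin, was 5.72-fold lower (329 to 57.5, -2.51 ± 0.68) and Col18a1 3.52-fold lower (552 to 157, -1.81 ± 0.56), while Col8a1 was 2.05-fold higher (272 to 559, 1.04 ± 0.52). Of 38 genes 9 were at least 1.5-fold lower and 2 higher, with a median of -0.11 (percentile 1.70). It stayed below the central 95% in 6 of 10 alternatives, and the 4 exceptions were quantile normalization, loess, the stricter detection limit and unmatched lists.

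Of the 26 lists with a percentile, 5 had medians above the central 95% of matched random lists and 3 below it. For lists of genes that vary independently 1.3 would be expected. Genes of a list may vary together, so the excess does not set an effect of reduced Phf21a apart from a difference between cultures. The other lists lay inside. Some of these were below the central 95% under 1 alternative each. They were mitochondrial biogenesis (percentile 1.44) and mitosis (0.76) with averaged probe sets, endoplasmic reticulum stress without shared genes (1.06) and skeletal muscle against unmatched lists (0.515). Fatty acid and triglyceride synthesis was below it with the stricter detection limit (median -0.28 over 14 genes, percentile 1.08), and thermogenic genes were above it against unmatched lists (97.6). Glycolysis and glucose uptake had 0 of 18 genes at least 1.5-fold higher and 4 lower (median -0.15, percentile 3.69), and its median was below the central 95% in 4 of 10 alternatives. Pfkl, the liver-type phosphofructokinase, was lowest (3049 to 1183, -1.37 ± 0.45). Pgam1, a phosphoglycerate mutase (13724 to 7924, -0.79 ± 0.29), and Pdk1, a pyruvate dehydrogenase kinase (1864 to 1084, -0.78 ± 0.47), were picked after their values were seen. The dim Eno2 had signals of 80.3 and 34.0, the latter under the detection limit, and was at -0.65 with both raised to it. Cholesterol synthesis and uptake had 2 of 20 higher and 0 lower (median 0.20, percentile 91.8). Ebp, a sterol isomerase, was at 1.09 ± 0.44, and Hmgcs1 was at 0.72 ± 0.29, although another of its 5 probe sets gave -0.40. Insulin and IGF signalling had 3 of 20 higher and 6 lower (median -0.16, percentile 7.25). Pde3b, the phosphodiesterase of insulin's antilipolytic action, was 3.19-fold lower (210 to 65.8, -1.67 ± 0.70). Igfbp4 was at -1.35 ± 0.53 with probe sets from -1.55 to 0.42.

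Responses to the induction mix and to stress also lay inside. Glucocorticoid and cAMP genes had 2 of 24 at least 1.5-fold higher and 2 lower (median 0.12, percentile 76.5), with Fam107a and Lcn2 (1.02 ± 0.47) furthest from 0. Endoplasmic reticulum stress and ATF4 targets had 0 of 27 higher and 3 lower (median -0.06, percentile 13.7). The amino acid transporter Slc7a5 was 2.69-fold lower (1095 to 407, -1.43 ± 0.53) and Xbp1 was at -0.77 ± 0.42. NRF2 and oxidative stress genes had 2 of 20 higher and 1 lower (median 0.22, percentile 95.9). Gsta4, a glutathione transferase, was 3.58-fold lower (7878 to 2200, -1.84 ± 0.36) and Mgst1, another, was at 0.78 ± 0.29. Smooth muscle, cytoskeleton and YAP or SRF targets had 4 of 18 higher and 2 lower (median 0.21, percentile 92.4), with Tagln at 1.04 ± 0.53 and Ankrd1 at 0.90 ± 0.52.

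Neuronal genes repressed through REST stayed largely undetected, with 6 of 31 past the detection limit. Of these 0 were at least 1.5-fold higher and 3 lower (median -0.63, percentile 3.93), and the median was below the central 95% in 3 of 8 alternatives. Tubb3 was at -1.02 ± 0.70, and Vgf had signals of 55.9 and 4.76, detected on the control array alone. Markers of other cell types were few and dim. Skeletal muscle markers were detected in 5 of 15 cases, with 0 higher and 3 lower (median -0.80, percentile 15.2). Ckm (55.5 and 22.5) and Actn2 (52.7 and 4.13) were past the detection limit on the control array alone. Endothelial markers were detected in 3 of 14 cases, where Egfl7 had signals of 14.6 and 69.3, with another probe set at -0.29, and Flt1 had 69.1 and 10.97. Osteoblast and chondrocyte markers were detected in 3 of 13 cases, where Sp7 had signals of 109 and 48.1, the latter under the detection limit, and Postn, a bright matrix gene, was at 0.78 ± 0.34. Reference genes had 2 of 16 higher and 0 lower (median 0.08, percentile 68.1). The highest were Gusb, a lysosomal glucuronidase (0.77 ± 0.41), and B2m (0.69 ± 0.29).

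**Figure D3:**
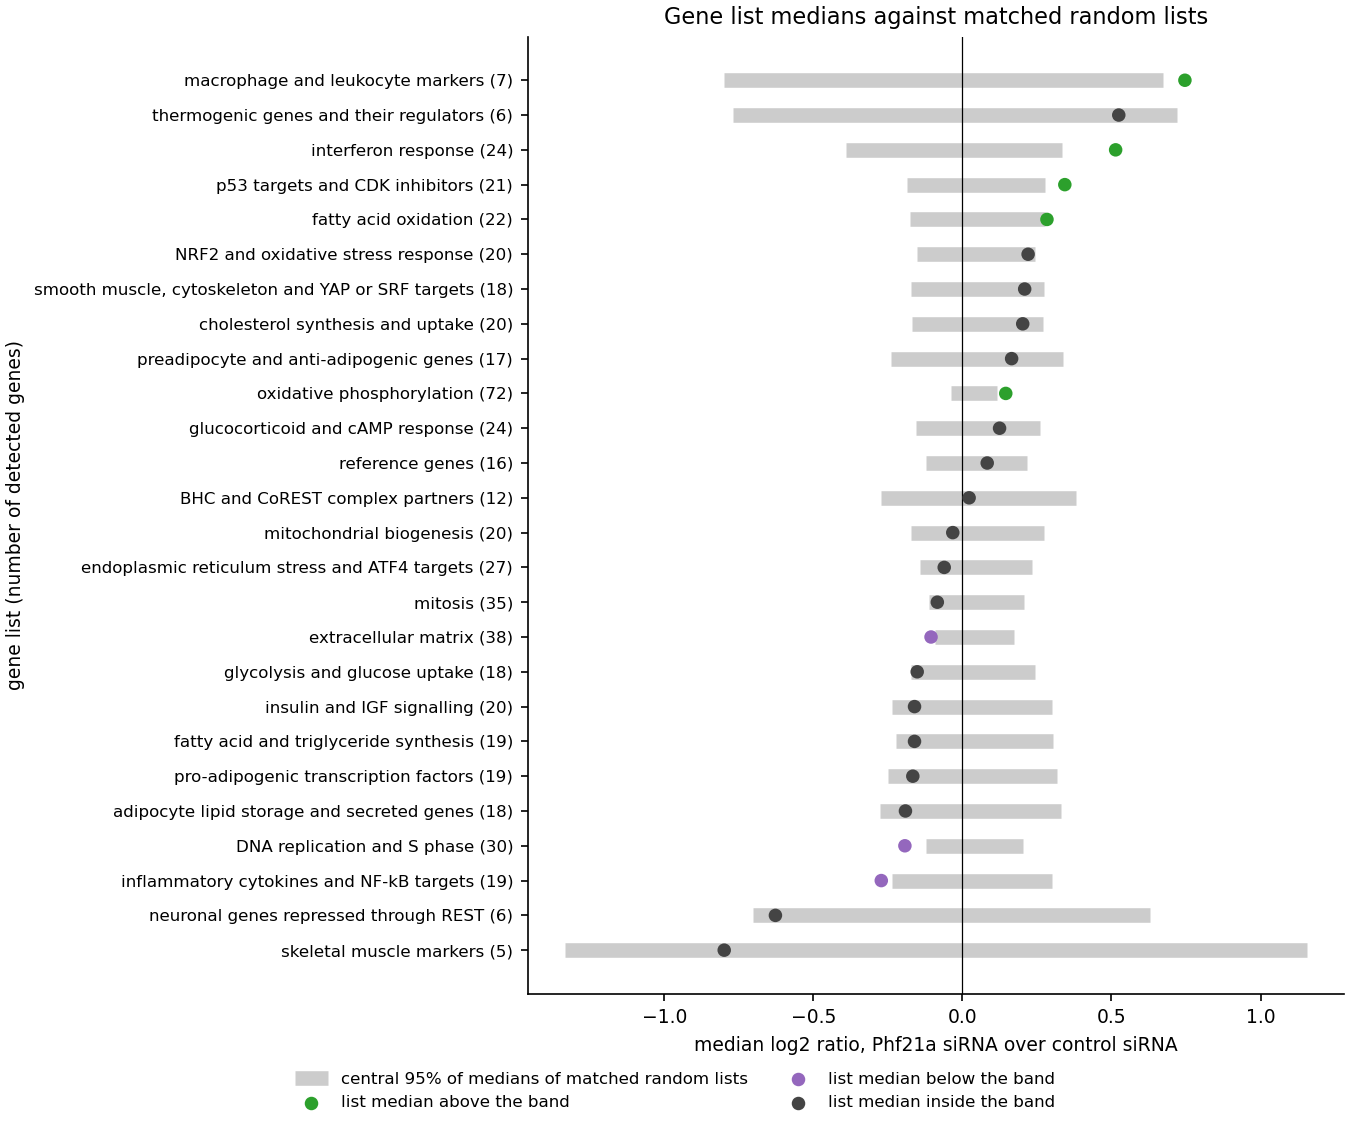
Median log2 ratio (points) of the 26 gene lists with at least 5 detected genes, Phf21a siRNA over control siRNA, against the central 95% of medians of 10000 random lists matched on signal (grey bars), with the number of detected genes in brackets. Green points lie above the bar, purple ones below and dark ones inside; medians run from -0.80 to 0.75.

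Directions above are relative to the authors' scaling, which set both arrays to the same trimmed mean. Control RNAs did not share it. Poly-A control transcripts, bacterial RNAs added to the sample before labelling, were higher on the Phf21a siRNA array in all 24 probe sets, with a median log2 ratio of 0.73 (SD 0.14). Hybridisation controls, added after labelling, were higher by a median of 0.23 (SD 0.08, 18 probe sets), and the 3 probe sets of 18S ribosomal RNA by 0.79. Scaled to the poly-A controls, the median log2 ratio of all genes moved by -0.74 and 80 genes were at least 2-fold higher and 3161 lower. Scaled to the hybridisation controls it moved by -0.24, with 330 higher and 1013 lower. Among genes past 2-fold, those higher made up 51.0% as the authors scaled the arrays, 2.47% under poly-A scaling and 24.6% under hybridisation scaling. Both scalings multiply 1 array by a single factor, which leaves 1 and 7 list medians above 0. RNA integrity was similar on both arrays. The ratio of 3' to 5' signal was 1.15 and 1.22 for Actb and 0.792 and 0.816 for Gapdh, control siRNA first.

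**Figure D4:**
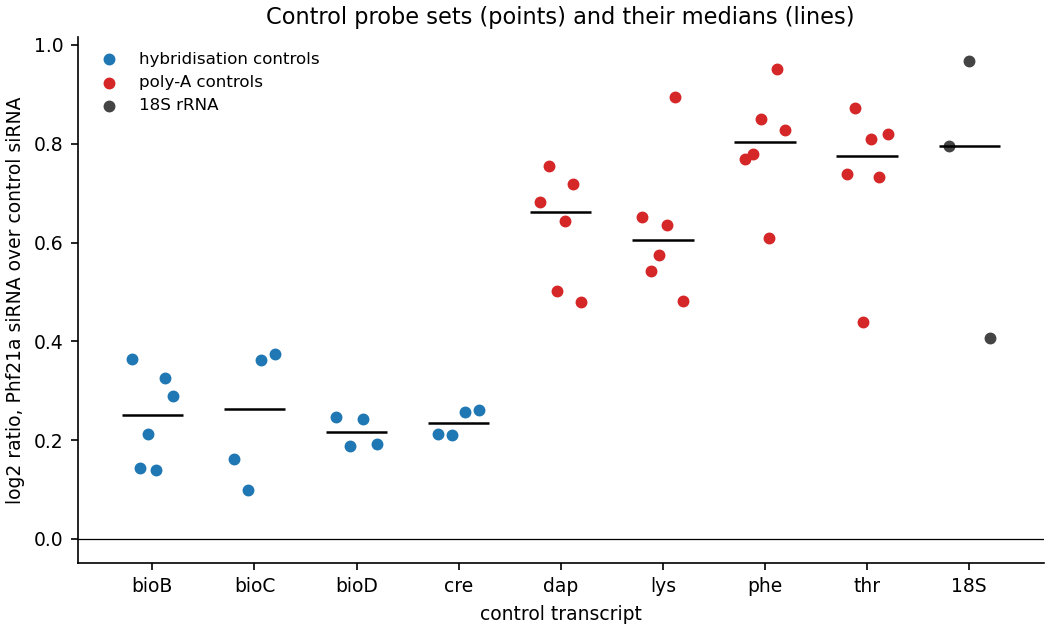
Log2 ratio of Phf21a siRNA over control siRNA for each probe set of the control transcripts (points, coloured by kind) with the median of each transcript (lines), 1 array per group. Hybridisation controls lie near 0.23, and the 4 poly-A transcripts have medians from 0.60 to 0.80.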

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

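The tests of the control RNAs, of the energy expenditure genes and of a duplex response or leukocytes were chosen after the result was seen, and the test of bright interferon genes before. Control RNAs outside the gene comparison differed between the arrays: the median log2 ratio (Phf21a siRNA over control siRNA) was 0.73 for the poly-A controls and 0.79 for 18S ribosomal RNA. A difference at hybridisation, scanning or scaling would move the hybridisation controls as much, but the medians lay 0.50 apart, more than the 0.33 that is 2 SD of the probe sets of both kinds. More spike mix in the Phf21a siRNA sample, which would leave 18S RNA in place, cannot be told apart from less messenger RNA per total RNA with 1 array per group. Among probe sets of like signal 1 of the 18S probe sets was inside the central 68%, at percentile 76.5, and the others stood at 92.6 and 94.7, which neither places 18S RNA with other RNAs nor apart from them. Less messenger RNA would put the spikes and 18S above the hybridisation controls, as they were (lowest spike median 0.60 against 0.23), but that explanation was drawn from these values.

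The energy expenditure genes Ppargc1a, Slc27a1, Pdk4 and Pnpla2 were higher together. An offset from array scaling stays open as part of it: scaled to the poly-A controls their median of 1.48 became 0.75, with 2 of the 4 at least 1.5-fold higher. For Ppargc1a, noise of single dim probe sets is argued against: with signals raised to the detection limit, its 4 other detected probe sets were higher by a log2 ratio of at least 1.76, beyond 1.28, which is 2 times their largest local spread. For Slc27a1, Pdk4 and Pnpla2, which had 1 other detected probe set between them, such noise stays open. A difference between the cultures or an off-target effect of the siRNA cannot be told apart from an effect of reduced Phf21a with 1 array per group.

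The interferon list had a median of 0.51. Noise of dim probe sets stays open as a source. In the list's 5 bright genes the median was 0.21, at percentile 76.7 of matched random lists, as such noise predicts. But 5 genes are too few to decide, and the full list stood at percentile 99.8 of lists matched on signal. With signals raised to the detection limit the full list's median was 0.086 (percentile 82.2). In the 18 members outside the duplex genes below, split off after the result was seen, it was 0.38 (percentile 99.8). Leukocytes in the Phf21a siRNA culture stay open as a source. Ptprc, Tyrobp, Lyz2, Cd52 and Laptm5, abundant in such cells, gained a median signal of 1.65 and at most 18.3. The 11 interferon genes at least 1.5-fold higher gained a median of 70.0 over the detection limit. With 2 local spreads added the 5 leukocyte genes had a median of 6.89, although Lyz2 then reached 72.6. The comparison cannot decide, because signals of different probe sets share no common scale and the 5 genes were chosen after the result was seen. Ptprc, Tyrobp and Cd52 were undetected on both arrays. Of the 7 detected leukocyte markers 4 were at least 1.5-fold higher, Csf1r and Cd14 among them, and 1 was lower. Both cultures received an siRNA, so an innate response to the RNA duplex would cancel in the ratio where it was equal. Only a stronger response to the Phf21a siRNA could raise the list, and genes such as Ifit1 and Cxcl10 most. With signals raised to the detection limit the 6 detected genes of that kind had a median of -0.19 (percentile 30.2 of matched random lists), with 1 above 0. The 18 other interferon genes had a median of 0.38, with 7 at least 1.5-fold higher and 0 lower. The genes of that kind were thus lower by 0.57, where such a response predicts them at or above the others. That prediction was not met, but the difference was within the 0.60 that is 2 SD of it among random lists. A stronger response to the Phf21a siRNA therefore stays open.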

How the results depend on the processing

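Scaling to control RNAs was tried only after the data were seen. No paired analysis was possible because each group had 1 array, and leaving out a replicate was not possible for the same reason. Phf21a was lower under all 9 alternatives run for it, from -1.34 to -1.14. For Phf21a, the named genes and the list medians compared here, the shift of the median of all genes was taken out under control scaling. Of 1358 values of named genes under alternatives 1329 moved by less than the local spread, 28 by more and 1 reversed: Egfl7, to -0.27 under poly-A scaling with the shift of the median of all genes taken out. Of 375 list medians 354 moved by less than the scatter of random lists and 21 by more. Neither unmatched random lists, which leave a list's median unchanged, nor median centring, which moves all medians alike, could add to the 21. Of the 24 highest and lowest genes 17 to 24 were among them under each alternative. Counts of genes at least 2-fold higher and lower were 259 and 240 with the stricter detection limit, 1023 and 1262 with none, 80 and 3161 under poly-A scaling and 330 and 1013 under hybridisation scaling. They were 1707 and 1570 at 1.5-fold, 188 and 207 at 3-fold, and 71 and 79 where all probe sets had to pass; with the higher floor they were 468 and 376. The interferon median was 0.086 with the higher floor, 0.21 with the stricter detection limit and with none, and, with that shift taken out, 0.11 under poly-A and 0.16 under hybridisation scaling. Averaging probe sets gave medians of 0.0018 for preadipocyte, -0.24 for mitochondrial biogenesis, -0.29 for glycolysis, -0.18 for mitosis, -0.20 for extracellular matrix, -0.038 for glucocorticoid and -0.016 for reference genes. Without a detection limit the thermogenic, neuronal and leukocyte medians were 0, where undetected genes sit at the floor. The skeletal muscle median was -0.13 with the higher floor. Values left with 1 detected gene were 0.48 for the neuronal list with the stricter limit, -2.43 for the endothelial list without suffixed probe sets and -1.17 for the osteoblast list without shared genes. Without shared genes the lipid storage median was -0.0093 and that of endoplasmic reticulum stress -0.19. Counts under another fold or filter follow from how many genes it admits, and those under control scaling from the shift; for the list medians the cause was not tested. Signal limited the rest: below a mean signal of 64 the local spread was 1.25.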

Other observations

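Lysosomal genes were higher after Phf21a siRNA. Hexa, a subunit of beta-hexosaminidase, was 2.54-fold higher (1763 to 4480, log2 ratio 1.35 ± 0.42) and Gla, an alpha-galactosidase, 2.90-fold higher (1251 to 3624, 1.53 ± 0.43). The sialidase Neu1 was 3.19-fold higher (243 to 776, 1.67 ± 0.54) and Npc1, which exports cholesterol from lysosomes, was at 1.21 ± 0.53. Atp6v0d1, a subunit of the proton pump, was 2.34-fold higher (2998 to 7002, 1.22 ± 0.34), whereas the abundant membrane protein Lamp1 was at 0.46 ± 0.29. These genes were picked after their values were seen.

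The idea came from Gusb and Atp6v0d1, both at least 1.5-fold higher. A list of other lysosomal genes, none of which the fixed lists held, was then written together with its prediction before its median was seen. Whether values of single members had been seen by then is not recorded, so the list is not shown to be independent of these data. Of its 55 genes on the array 53 were detected, 45 of them above 0, with 17 at least 1.5-fold higher and 1 lower. Their median of 0.45 lay above the central 95% of matched random lists, which ran from -0.09 to 0.17. It was 0.42 with loess, 0.46 with averaged probe sets and 0.47 without suffixed probe sets. Under poly-A scaling it was -0.28, where the median of all genes was -0.71. The result is consistent with a coordinated difference in lysosomal genes between these 2 cultures, as a hypothesis: with 1 array per group a difference between cultures unrelated to Phf21a stays open.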
